A study of Mus musculus with 6 samples.

How the data were processed

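The series measured polyadenylated RNA of bone marrow mesenchymal stromal cells from C57/B6J mice. Per the protocols in the labels, cells flushed from the femur were cultured in low glucose medium with serum and exposed to 3 µg/mL LPS for 24 h, mRNA was selected with oligo(dT), libraries were made with dUTP marking of the second strand, and paired reads of 150 bases were sequenced on an Illumina NovaSeq, per the series text. The 6 libraries analysed here form 2 groups of 3, WT with LPS and Nlrp3 knockout with LPS; unstimulated cultures, which the protocol mentions, were not analysed here. The sample titles number the libraries of each group as day 1, 2 and 3, while another label gives day 1 for all 6. The number was therefore used only to name replicates and, in an alternative fit, as a block.

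Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d with the mouse build GRCm38. The counting step, the annotation release, whether counting used the strand and any filter are not given in the sources used here, so that overlapping and antisense genes and members of gene families with shared sequence cannot be separated with certainty. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to library size, per the file headers), given to 2 decimals, together with estimated counts per gene, for 55401 genes. The deposited counts are whole numbers but are estimates: over 5834 genes with an FPKM of at least 5 and at least 300 counts, the ratio of count to FPKM was compared with that of the first library, and 100% of these comparisons lay within 1% of a single factor per library, and 44.4% of the counts up to 16 were 4, 8, 12 or 16, against 25% if each value were as frequent. A fragment of 2 reads of 150 bases thus gives 4 counts when bases are divided by 75, which is an inference from the values. Over the 5834 genes compared, counts and FPKM hence carry the same information. The totals of 53.2 to 66.3 M estimated counts per library (M, 1e6) correspond to about 13.3 to 16.6 M fragments. A floor of 3 fragments, or 12 estimated counts, over the 3 libraries of a group was used where all were at 0; the floor covers counting error only. The 20 most abundant genes took between 11.03% and 11.6% of the counts of a library, and mitochondrial genes between 1.77% and 3.18%. Coordinates are those of the table; 94.2% of the 55141 gene IDs shared with GENCODE M21 have the same start and end there.

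Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, two-sided, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05). This test was kept as the main one, as fixed before the data were examined, because the counts are estimates that were proportional to the FPKM in the genes compared. The estimated counts were tested with the quasi-likelihood test of edgeR 4.0.16 and with DESeq2 1.42.0 as alternatives. Nlrp3 was also compared with an exact two-sided permutation test. Tested genes within 10 Mb of Nlrp3, Nlrp3 left out, were compared with all others by Fisher's exact test.

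There were 36 gene lists with 960 entries, fixed before the data were examined, of which 959 were matched to the table, 25 of them through an older symbol. They cover the inflammasome, the TLR4 and NF-κB response, TLR4 signalling, chemokines, interferon response, MHC class I presentation, immunomodulators, osteogenic, adipogenic and chondrogenic genes, matrix genes, matrix proteases, contractile genes, cell cycle, p53 and senescence, cell death, unfolded protein response, glycolysis and hypoxia, respiratory chain, antioxidant response, sterol synthesis, autophagy and lysosome, WNT, TGF-β and BMP pathways, handling and RNA quality (immediate early, mitochondrially encoded, ribosomal protein and histone genes) and markers of stromal cells, macrophages, granulocytes, lymphoid cells, dendritic cells, osteoclasts, erythroid and megakaryocytic cells, mast cells and basophils, and endothelium. Lists with at least 3 tested genes (32 lists) were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those lists; camera with an estimated correlation and fry were alternatives. KEGG pathways and GO terms given in the table, with 15 to 300 tested genes, were tested with camera and adjusted per collection.

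Further tests were chosen after results were seen. Chromosome medians were compared with rotations of the fold changes along the genome, adjusted over 20 chromosomes, also after a fit on transcript GC content. The ratios of macrophage genes were compared with Cochran's Q, with each gene's error averaged with the median error. The interval of the Hoxb median comes from 10000 bootstrap draws.

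Genes named in the text follow a rule fixed before the data were examined: Nlrp3; the 10 highest and the 10 lowest log2 fold changes among genes past the threshold whose groups did not overlap, leaving out predicted, clone-named and pseudogene symbols; and up to 4 members of each list with the largest absolute change among those past the threshold, or, where none passed, up to 2 with the smallest p. A gene that this rule names is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

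The alternatives were pseudocounts of 0.1 and 0.5, no filter beyond a value above 0, a filter at an FPKM of 5, 3 other scalings (median of ratios, quantile, upper quartile), eBayes without a trend, robust eBayes, array quality weights, the replicate number as a block, each library left out in turn, a 2-fold threshold, an adjusted p of 0.01, and windows of 5 and 20 Mb around Nlrp3. Tests with edgeR on the counts divided by 4, and edgeR and DESeq2 values for single genes, were added after seeing the data.

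The procedures were tested on simulated data drawn for this comparison from the real means and library sizes, with 67 genes changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. Among 12059 genes tested, limma recovered 17.9%, 62.7% and 100% of them, and 4% of its calls were false. Among 17595 genes, edgeR recovered 25.4%, 77.6% and 100% with 3.57% false calls. Among 25092 genes, DESeq2 recovered 32.8%, 82.1% and 100%, and 17.3% of its calls were false. Of 30 simulated unchanged lists, camera called 1 at the preset correlation and 0 with an estimated correlation, and a list of 20 genes raised by 1.5-fold had adjusted p-values of 5.18e-17 and 0.0205. The simulated genes were drawn independently of each other, so that these lists do not test whether the preset correlation is adequate for the real genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.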

Results

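RNA sequencing was carried out on mesenchymal stromal cells grown from mouse femoral bone marrow, a plastic-adherent culture of connective tissue progenitors that can also hold marrow macrophages. Cultures of wild-type (WT) and Nlrp3 knockout mice were exposed for 24 h to 3 µg/mL lipopolysaccharide (LPS), the bacterial outer membrane component sensed by TLR4. Nlrp3 encodes the sensor of an inflammasome, a complex that activates caspase-1 and the maturation of interleukin-1 beta. The data analysed here comprised 6 libraries, 3 WT and 3 knockout, all exposed to LPS, so that the comparison addressed how the transcriptomes of the genotypes differed under LPS and not how either genotype responded to it. The estimated counts assigned to genes summed to between 53.2 and 66.3 M per library (M, 1e6), which corresponds to about 13.3 to 16.6 M fragments, and between 11713 and 12089 genes reached an FPKM of 1. The labels do not say whether the 3 libraries of a genotype came from separate animals or separate cultures, so that the p-values measure only the spread between these libraries, which may be technical. If each genotype stems from a single starting culture, differences between the cultures cannot be told apart from an effect of the genotype. This holds for every gene called below. Correlations of log2(FPKM + 1) lay between 0.974 and 0.985 within a genotype and between 0.943 and 0.952 across genotypes, and the first principal component, which held 61.0% of the variance, separated the genotypes. Unless stated otherwise, levels below are mean FPKM ± SD of 3 libraries, fold changes are knockout minus WT on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

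The targeted gene was examined first. Nlrp3 (ENSMUSG00000032691, GRCm38 chromosome 11, positions 59541568 to 59566956, plus strand) had FPKM values of 2.76, 1.68 and 1.86 in WT replicates 1, 2 and 3, from 730, 502 and 444 estimated counts. It had 0 estimated counts in each of the 3 knockout libraries. Against a floor of 12 estimated counts, equal to 3 fragments, over the 3 knockout libraries together, Nlrp3 was at least 142-fold lower in the knockout cultures. The exact two-sided permutation test of the difference gave p = 0.1, the smallest value that 3 libraries against 3 allow, and limma gave an adjusted p of 0.000408. Every library therefore carried the Nlrp3 level that its label names.

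Of 12136 genes tested, 1264 were higher and 1117 were lower in the knockout cultures at an adjusted p of 0.05 (limma). Among them 297 were higher and 227 lower by at least 2-fold. The quasi-likelihood test of edgeR on the estimated counts called 1483 genes higher and 1419 lower among 17479 tested, and 2143 of the 2381 limma calls were also edgeR calls. The median absolute log2 fold change of the called genes was 0.60. The values of the 3 knockout libraries did not overlap those of the 3 WT libraries for 36.7% of the tested genes, against 10% by chance. With 1 library left out, the number of lower genes was 583, 675 and 640 without WT replicate 1, 2 and 3, and the number of higher genes was 705 without knockout replicate 1.

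The 10 genes with the largest increases were examined singly. Glipr1, which encodes a secreted CAP-family protein, rose from 3.19 ± 0.53 to 87.05 ± 8.1 FPKM (log2 fold change 4.4 ± 0.11 SE, adjusted p = 3.75e-06), and Timp3, an inhibitor of matrix metalloproteinases, rose from 15.6 ± 0.95 to 131.8 ± 4.0 (3.00 ± 0.07, adjusted p = 2.98e-06). Angptl7, a secreted angiopoietin-like protein, rose from 0.763 to 27.8, and the transcriptional cofactor Eya2 rose from 0.077 to 13.4. Col2a1, the fibrillar collagen of cartilage, rose from 0.280 to 14.04. Cdsn, which encodes corneodesmosin, rose from 0.893 to 18.1, Igfbp5, an insulin-like growth factor binding protein, from 0.347 to 10.5, and the protease inhibitor Serpinb6b from 0.093 to 7.62. The largest log2 fold changes of these 10 genes belonged to Rpl39l (0.097 to 41.8 FPKM, 5.29 ± 0.12) and Rps4l (0.303 to 35.9, 4.81 ± 0.12), ribosomal protein genes with near-identical parent genes. Their parent genes were chosen after their values were seen. Rpl39 stood at 123.3 ± 4.0 in WT and 115.9 ± 17.4 in knockout libraries, and Rps4x at 593 ± 35 and 622 ± 59, and neither passed. The 10 genes that rose most had adjusted p-values of 2.4e-05 or smaller (limma), and each was higher in 3 of 3 knockout libraries than in every WT library. A call and groups that do not overlap were required by the rule that chose them, so that neither is further evidence.

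The 10 genes with the largest decreases were examined in the same way. Crabp1, a cellular retinoic acid binding protein, fell from 357 ± 43 to 11.7 ± 2.5 FPKM (log2 fold change -4.83 ± 0.16, adjusted p = 1.28e-05). Tnmd, which encodes tenomodulin, a tendon marker, fell from 28.6 ± 0.81 to 0.2 ± 0.096 (-4.63 ± 0.08, adjusted p = 1.48e-06). Igfbp3 fell from 35.1 to 0.883, the matrix gene Efemp1 from 42.0 to 1.38, Ndufa4l2, a hypoxia-inducible mitochondrial protein, from 33.8 to 1.15, and Irx1, a homeobox transcription factor, from 12.3 to 0.007. Mmp9, the gelatinase, fell from 139 ± 6.8 to 9.15 ± 0.49, Cxcl5, a neutrophil chemokine, from 330.0 ± 11.4 to 28.3 ± 3.6, and Ccl8 from 13.3 to 0.583. Thy1, a surface marker used to identify stromal cells, fell from 134 ± 6.2 to 11.8 ± 1.2. The adjusted p-values of these 10 genes lay between 1.48e-06 and 0.000116 (limma).

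**Figure D1:**
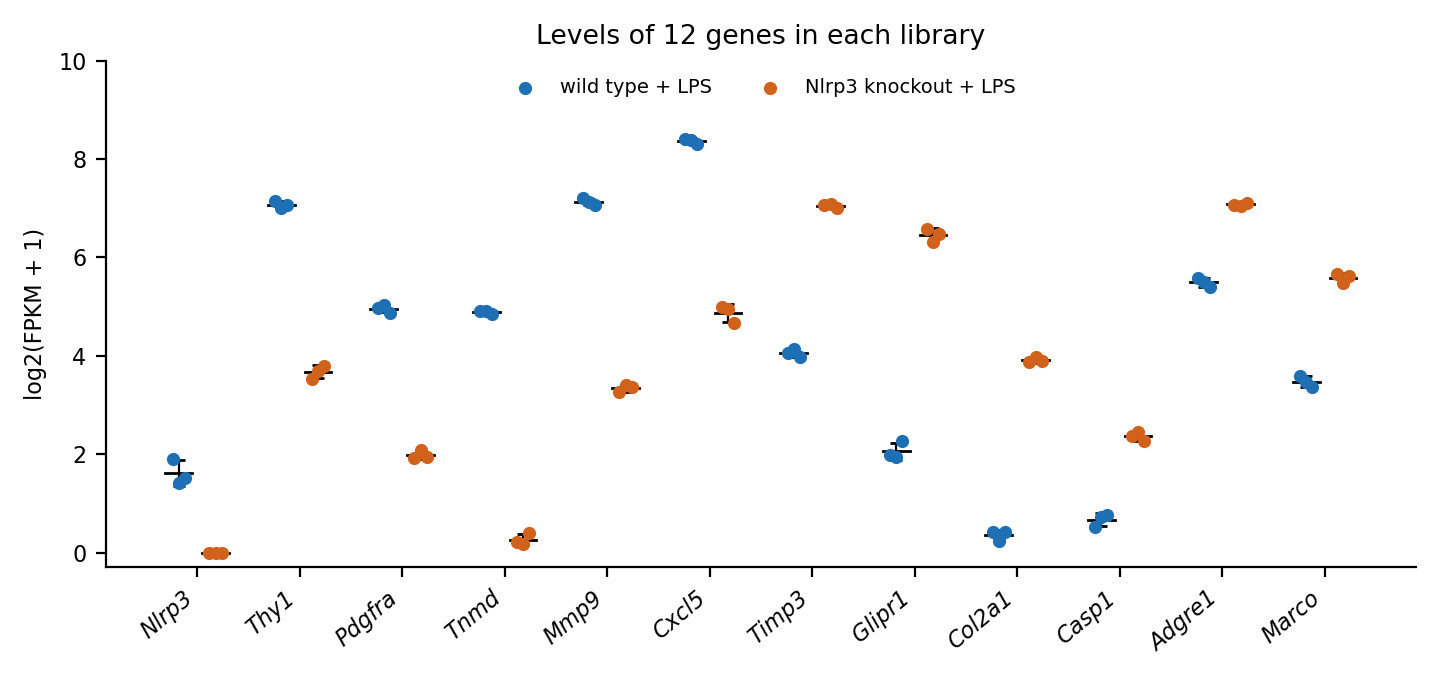
Level of 12 genes in the 6 libraries, as log2(FPKM + 1) on the vertical axis. Each point is a library (blue, WT with LPS; orange, Nlrp3 knockout with LPS), horizontal lines are means of 3 libraries and bars are SD. Nlrp3 lies at 0 in the 3 knockout libraries. For every gene drawn the libraries of the genotypes do not overlap, which held for all 2381 called genes.

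Markers of stromal cells moved in both directions. Of 21 tested, 5 rose and 8 fell, and the counts were the same adjusted over the list alone. Besides Thy1, the platelet-derived growth factor receptor Pdgfra fell from 30.2 ± 1.7 to 2.96 ± 0.23 FPKM (-2.98, adjusted p = 3.75e-06), Ly6a, which encodes Sca-1, from 188 ± 71 to 46.1 ± 5.9 (-1.95, adjusted p = 0.00212) and the transcription factor Twist2 from 9.82 ± 0.35 to 1.87 ± 0.34 (-1.92, adjusted p = 5.32e-05). Among the members that rose were Nes (nestin), from 11.1 to 33.7, and Nt5e, which encodes CD73, from 0.183 to 2.35; Nes was chosen after its values were seen. The list as a whole did not pass (camera adjusted p = 0.207), but passed downwards without knockout replicate 1 or 3 (0.0485 and 0.0458). As given below, 25 of 26 macrophage markers were higher in the same knockout libraries. Whether this bears on the stromal markers was not tested.

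Genes of the inflammasome moved in both directions as well. Of 20 tested, 4 rose (5 adjusted over the list alone) and 4 fell, Nlrp3 among them (camera adjusted p = 0.931). The mean log2 fold change of the list was 0.02 and camera gave the upward direction. Casp1, which encodes caspase-1, rose from 0.593 ± 0.136 to 4.16 ± 0.32 FPKM (1.70, adjusted p = 8.41e-05) and the alarmin Il33 from 0.357 ± 0.071 to 3.24 ± 0.32 (1.64, adjusted p = 7.99e-05). The interleukin-1 receptor Il1r1 fell from 12.1 ± 1.1 to 2.89 ± 0.09 (-1.75, adjusted p = 3.74e-05). The cytokines Il1b (107 ± 9.4 to 239 ± 24) and Il1a (45.3 ± 2.5 to 137 ± 24), named after their values were seen, were the other members that rose. Il18, also chosen after its values were seen, stood at 3.85 ± 0.65 and 3.65 ± 0.80. In the same libraries 25 of 26 macrophage markers were higher, as given below, and macrophages express Casp1 and interleukin-1 genes.

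Targets of TLR4 and NF-κB also split. Of 36 tested, 12 rose and 6 fell (14 and 7 adjusted over the list alone, camera adjusted p = 0.163). Csf3, the granulocyte colony-stimulating factor, rose from 2.62 to 19.1 FPKM (2.48, adjusted p = 3.04e-05) and Nos2, the inducible nitric oxide synthase, from 9.48 to 38.3 (1.91, adjusted p = 2.26e-05), whereas Steap4, a metalloreductase, fell from 16.7 to 2.30 (-2.43, adjusted p = 1.66e-05), as did Mmp9. Of 23 components of TLR4 signalling, 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.1). The LPS co-receptor Cd14 rose from 35.6 to 69.2, Tlr2 from 14.3 to 26.3 and Ikbkg, the regulatory subunit of the IκB kinase complex, from 3.23 to 6.53, and the LPS binding protein Lbp fell from 3.41 to 1.79. Of 20 chemokines, 8 rose and 7 fell, also adjusted over the list alone; their median and mean log2 fold changes were -0.02 and -0.05, while camera gave the upward direction (adjusted p = 0.927). Cxcl9, an interferon-induced chemokine, fell from 54.5 ± 2.9 to 7.62 ± 1.09 (-2.69, adjusted p = 1.93e-05), next to Cxcl5 and Ccl8, and Cxcl2 rose from 10.3 ± 1.2 to 54.5 ± 5.0 (2.30, adjusted p = 3.57e-05). Of 25 immunomodulatory products attributed to stromal cells, 9 rose and 3 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.0447, and adjusted p = 0.233 with an estimated correlation). That call was also lost without WT replicate 1 or 2 (0.0601 and 0.0709) and without knockout replicate 1 or 2 (0.0525 and 0.121). Besides Nos2 and Nt5e, Tgfb2 rose from 1.88 to 6.84 and Ptges, a prostaglandin E synthase, from 9.60 to 18.0. Cd14, Csf3 and Nos2 are expressed by macrophages, whose markers were higher in the same knockout libraries.

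Interferon-stimulated genes were lower in the knockout cultures. Of 44 tested, 25 fell and 1 rose (30 and 1 adjusted over the list alone), with a median log2 fold change of -0.43 (camera adjusted p = 5.77e-12, and adjusted p = 0.111 with an estimated correlation). The interferon-inducible GTPases Iigp1, Ifi47 and Tgtp1 fell from 13.0 to 4.31, from 40.1 to 17.2 and from 20.1 to 8.91 FPKM, and Trim30a fell from 21.5 to 7.73. Of 23 genes of MHC class I presentation, 14 fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 1.03e-06, and adjusted p = 0.283 with an estimated correlation). The class I genes H2-K1 and H2-T23 fell from 148 ± 4.9 to 78.9 ± 13.0 (-0.91, adjusted p = 0.00293) and from 60.0 ± 3.4 to 31.8 ± 4.2 (-0.90, adjusted p = 0.00161). H2-Q4 fell from 65.9 to 24.2 and H2-Q6 from 3.73 to 1.10, both uncertain because genes of the H2-Q family share sequence. These decreases stood beside the increase of 25 of 26 macrophage markers, and a link between them was not tested.

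Macrophage markers were higher in the knockout cultures. Of 33 matched markers 26 passed the expression filter. Of these, 25 rose, also adjusted over the list alone, and the remaining gene was not called. Ptprc, which encodes CD45, was among the markers below the filter. It stood at 0.303 ± 0.040 FPKM in WT and 0.843 ± 0.316 in knockout libraries, and was chosen after its values were seen. The median log2 fold change of the 26 tested genes was 0.94 (camera adjusted p = 5.51e-17, and adjusted p = 0.117 with an estimated correlation). The scavenger receptor Marco rose from 10.2 ± 0.88 to 47.2 ± 3.1 FPKM (2.11 ± 0.09, adjusted p = 2.34e-05), the lectin receptor Clec4d from 12.1 ± 0.20 to 43.6 ± 3.3 (1.76 ± 0.07, adjusted p = 2.4e-05), Adgre1, which encodes F4/80, from 44.0 ± 2.7 to 134 ± 2.8 (1.59 ± 0.07, adjusted p = 2.9e-05) and the NADPH oxidase subunit Cybb from 10.2 ± 0.75 to 32.5 ± 3.9 (1.57 ± 0.10, adjusted p = 0.000139). The mean log2 level of the 26 genes lay between 3.59 and 3.69 in the WT libraries and between 4.55 and 4.69 in the knockout libraries. All 3 tested genes of the dendritic cell and MHC class II list rose, also adjusted over the list alone, namely Cd74 (2.73 to 6.01), H2-DMb1 (1.81 to 3.95) and H2-Ab1 (2.12 to 3.59; camera adjusted p = 0.00717, and adjusted p = 0.283 with an estimated correlation). H2-Ab1 did not pass without WT replicate 2 or 3 (limma adjusted p = 0.0629 and 0.0648). Of 5 granulocyte genes, S100a8 (0.783 to 4.50), Csf3r (1.36 to 5.40) and Mmp8 (0.910 to 3.36) rose and 2 fell, Mmp9 among them, with the same counts adjusted over the list alone. Their median log2 fold change was 1.19 and their mean -0.09, and camera gave the upward direction (adjusted p = 0.555). Of 7 osteoclast genes 4 fell (Mmp9, Itgb3, Acp5 and Tcirg1) and 3 did not pass, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0854). Itgb3 fell from 3.51 to 1.98 and Tcirg1 from 26.9 to 20.9. Acp5 (adjusted p = 0.0478) did not pass without WT replicate 1 (0.164), in edgeR (0.0796) or in DESeq2 (0.0629). With 1 library left out it passed only when that library was knockout replicate 3.

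Markers of other blood and vessel cells were mostly below the expression filter. Of the lymphoid list 3 genes were tested, of which Trac rose from 0.820 to 3.38 FPKM and Ebf1, a factor also expressed in stromal cells, fell from 5.99 to 3.00, with the same counts adjusted over the list alone (camera adjusted p = 0.679). The erythroid and megakaryocyte list had 2 tested genes of 18 matched, the platelet chemokines Ppbp (7.59 to 31.5) and Pf4 (52.1 to 124), and both rose. These 2 genes cannot tell whether cells of these lineages differed in number. The mast cell and basophil list had 2 tested genes, Gata2, which fell from 4.39 to 1.58, and Mcpt8, which rose from 0.783 to 1.79. The only tested endothelial marker, Eng, which is also a stromal marker, fell from 35.0 to 12.4. Adjusted over the list alone, the calls of the last 3 lists were the same; with fewer than 3 tested genes they received no set test.

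Contractile genes of smooth muscle and myofibroblasts were higher. Of 17 tested, 13 rose (15 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.46 (camera adjusted p = 5.5e-07, and adjusted p = 0.0717 with an estimated correlation). Acta2, smooth muscle actin, rose from 1156 ± 70 to 2338 ± 218 FPKM (1.014, adjusted p = 0.00182), Actg2 from 194 ± 32 to 444 ± 18 (1.20, adjusted p = 0.00123), Lmod1 from 14.3 to 27.4 and Synpo2 from 0.507 to 2.87. Of 33 collagens and other matrix genes, 19 fell and 7 rose, also adjusted over the list alone (camera adjusted p = 0.00186, and adjusted p = 0.283 with an estimated correlation). Dcn (decorin) fell from 17.4 ± 0.71 to 3.26 ± 0.38, the mineralization inhibitor Mgp from 148 ± 11 to 36.6 ± 6.4 and Fbn1 (fibrillin-1) from 177 ± 14 to 48.7 ± 4.9, and Ccn2 (connective tissue growth factor) rose from 239 ± 10 to 792 ± 57. In the same knockout libraries 25 of 26 macrophage markers were higher, and a link to the matrix genes was not tested. Of 25 matrix proteases and inhibitors, 11 rose and 8 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.1), with increases of Timp3, of the collagenase Mmp13 (10.1 to 34.0) and of the urokinase receptor Plaur (11.8 to 34.4).

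Lineage genes were also compared. Of 11 tested osteogenic genes, 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00844, and adjusted p = 0.169 with an estimated correlation). The list did not pass without knockout replicate 1, 2 or 3 (0.143, 0.214 and 0.153). Bmp4 rose from 0.017 ± 0.029 to 5.57 ± 3.59 FPKM (2.504 ± 0.44, adjusted p = 0.0089), Msx2 from 1.59 to 5.76 and Alpl, alkaline phosphatase, from 0.133 to 1.42, and Spp1 (osteopontin), which macrophages also express, fell from 1784 ± 109 to 775 ± 124 (-1.21, adjusted p = 0.00179). Of 12 adipogenic genes 4 rose and 1 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.884). Cd36 rose from 2.30 to 5.30, Cebpa from 1.95 to 4.51 and Dgat2 from 5.90 to 8.47, and the desaturase Scd1 fell from 76.0 to 32.0. Dgat2 (adjusted p = 0.0204) did not pass without WT replicate 1 or 3 (0.0837 and 0.0793) or knockout replicate 1 (0.0519). Of 5 chondrogenic genes, Col2a1 and Fmod (1.86 to 3.28) rose and Sox9 fell from 2.74 to 1.02, with the same counts adjusted over the list alone (camera adjusted p = 0.411). Of 29 genes of the WNT, TGF-β and BMP pathways, 14 rose and 6 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.0172, and adjusted p = 0.169 with an estimated correlation). It did not pass without knockout replicate 1, 2 or 3 either (0.214, 0.424 and 0.122). Wnt10b rose from 0.35 to 5.53, the secreted WNT modulators Sfrp2 and Dkk3 from 3.33 to 18.3 and from 19.8 to 83.7. The changes of these lineage and pathway genes stood beside the increase of 25 of 26 macrophage markers, without a test of a link.

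Genes of endoplasmic reticulum stress were higher and genes of sterol synthesis were lower. Of 23 tested genes of the unfolded protein response 18 rose, also adjusted over the list alone, and 5 did not pass, with a median log2 fold change of 0.53 (camera adjusted p = 3.98e-10, and adjusted p = 0.117 with an estimated correlation). The secreted factor Manf rose from 39.1 ± 2.3 to 85.9 ± 7.5 FPKM (1.11, adjusted p = 0.00028), Sdf2l1 from 27.9 to 61.1, Creld2 from 44.5 to 92.9 and the transcription factor Atf3 from 2.40 to 7.06. Atf3 also belongs to the immediate early list, of which 7 of 20 genes rose in the same libraries, as did 25 of 26 macrophage markers. Of 24 sterol synthesis genes 15 fell (19 adjusted over the list alone) and 9 did not pass, with a median log2 fold change of -0.49 (camera adjusted p = 1.48e-09, and adjusted p = 0.0675 with an estimated correlation). Fdft1, the squalene synthase, fell from 35.3 ± 2.1 to 16.8 ± 3.4 (-1.05, adjusted p = 0.00297), and the mevalonate pathway enzymes Pmvk and Mvd fell from 15.2 to 7.14 and from 23.9 to 12.5.

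Of 22 p53 target and senescence genes 10 rose and 3 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.0660, and 0.0477 and 0.0425 without knockout replicate 1 and 2). Cdkn2a, the locus of the cell cycle inhibitors p16 and p19Arf, fell from 235 ± 35 to 57.2 ± 5.6 FPKM (-2.02, adjusted p = 0.000141), while the p53 targets Cdkn1a (43.7 to 76.7), Pmaip1 (0.763 to 3.4) and Ccng1 (31.7 to 55.3) rose. Of 34 cell cycle genes 3 rose, namely Rrm2 (28.8 to 52.0), Cdc6 (3.32 to 4.79) and Tpx2 (27.6 to 32.8), and Cenpa fell from 8.48 to 6.85; 2 remained higher adjusted over the list alone (camera adjusted p = 0.121). Tpx2 and Cenpa lay near the threshold (adjusted p = 0.0328 and 0.0491) and neither passed without WT replicate 1 (0.12 and 0.0994). Cenpa did not pass whichever library was left out, and Tpx2 passed only when that library was knockout replicate 3. Tpx2 passed neither in edgeR (0.0568) nor in DESeq2 (0.0684). Of 21 cell death genes 2 rose and 3 fell (2 and 4 adjusted over the list alone), with a median log2 fold change of 0.06, a mean of -0.05 and the downward direction in camera (adjusted p = 0.884). The necroptosis kinase Ripk3 fell from 18.2 to 4.58, its partners Zbp1 and Mlkl from 49.3 to 28.4 and from 28.8 to 21.3, and Bcl2a1b, whose close paralogs can share its reads, rose from 12.4 to 17.0 (adjusted p = 0.0401). Bcl2a1b passed neither in edgeR (0.0876) nor in DESeq2 (0.0605), nor without any of the 3 knockout replicates (0.122, 0.0823 and 0.0784), and edgeR called 0 genes of this list higher. Of 29 antioxidant genes 12 rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.0838). The metallothioneins Mt1 and Mt2 rose from 56.9 to 127.7 and from 179 to 386, and Gpx3 and Gstm2 fell from 29.7 to 10.04 and from 83.0 to 39.9. Of 27 glycolysis and hypoxia genes 3 rose and 4 fell, also adjusted over the list alone; the mean log2 fold change was 0.01 and camera gave the downward direction (adjusted p = 0.884), with Car9 (0.320 to 2.32) and Pfkfb3 (4.62 to 12.6) higher and Adm (93.4 to 25.6) and the lactate transporter Slc16a3 (41.5 to 24.1) lower. Of 35 respiratory chain genes only Cycs changed, from 24.6 to 32.4, and it did not pass adjusted over the list alone (camera adjusted p = 0.182). Of 28 autophagy and lysosome genes only the protease Ctss, also a macrophage marker, changed, from 22.6 to 45.5, also adjusted over the list alone (camera adjusted p = 0.572).

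Lists that reflect handling and RNA quality were examined in the same way. Of 20 immediate early genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00509, and adjusted p = 0.345 with an estimated correlation), among them Fosl1 (7.38 to 21.3 FPKM), Egr3 (0.777 to 2.47) and Dusp1 (12.9 to 23.8). Without knockout replicate 3 the adjusted p of the list was 0.0508. None of 53 ribosomal protein genes was called by limma, also adjusted over the list alone; 2 were lower at an unadjusted p under 0.05, and edgeR called 1 lower. The list was nevertheless shifted downwards as a set, with a median log2 fold change of -0.15 (camera adjusted p = 0.00628, adjusted p = 0.788 with an estimated correlation, and 0.382 without knockout replicate 2); Rps20 stood at 79.6 ± 16.4 and 54.0 ± 6.0 and Rpl10a at 274 ± 29 and 182 ± 43. None of 13 mitochondrially encoded genes was called by limma, by edgeR, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.488), with mt-Nd1 at 1843 ± 81 and 2238 ± 386 and mt-Nd3 at 363 ± 87 and 475 ± 104. Without knockout replicate 3 the list passed upwards (adjusted p = 0.00328), as did mt-Nd1 (0.0471). The mitochondrial share of the counts was 3.18%, 2.9% and 1.77% in knockout replicates 1, 2 and 3 and 2.31%, 2.45% and 2.47% in the WT libraries. Of the histone list 2 genes passed the expression filter and neither was called by limma or edgeR, also adjusted over the list alone; 1 was lower at an unadjusted p under 0.05. H1f2 stood at 45.9 ± 0.43 and 37.0 ± 6.1 and H2bc4 at 41.4 ± 1.5 and 39.96 ± 5.7. H1f2 passed as lower without knockout replicate 3 (limma adjusted p = 0.0128) and with array quality weights (0.00601).

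**Figure D2:**
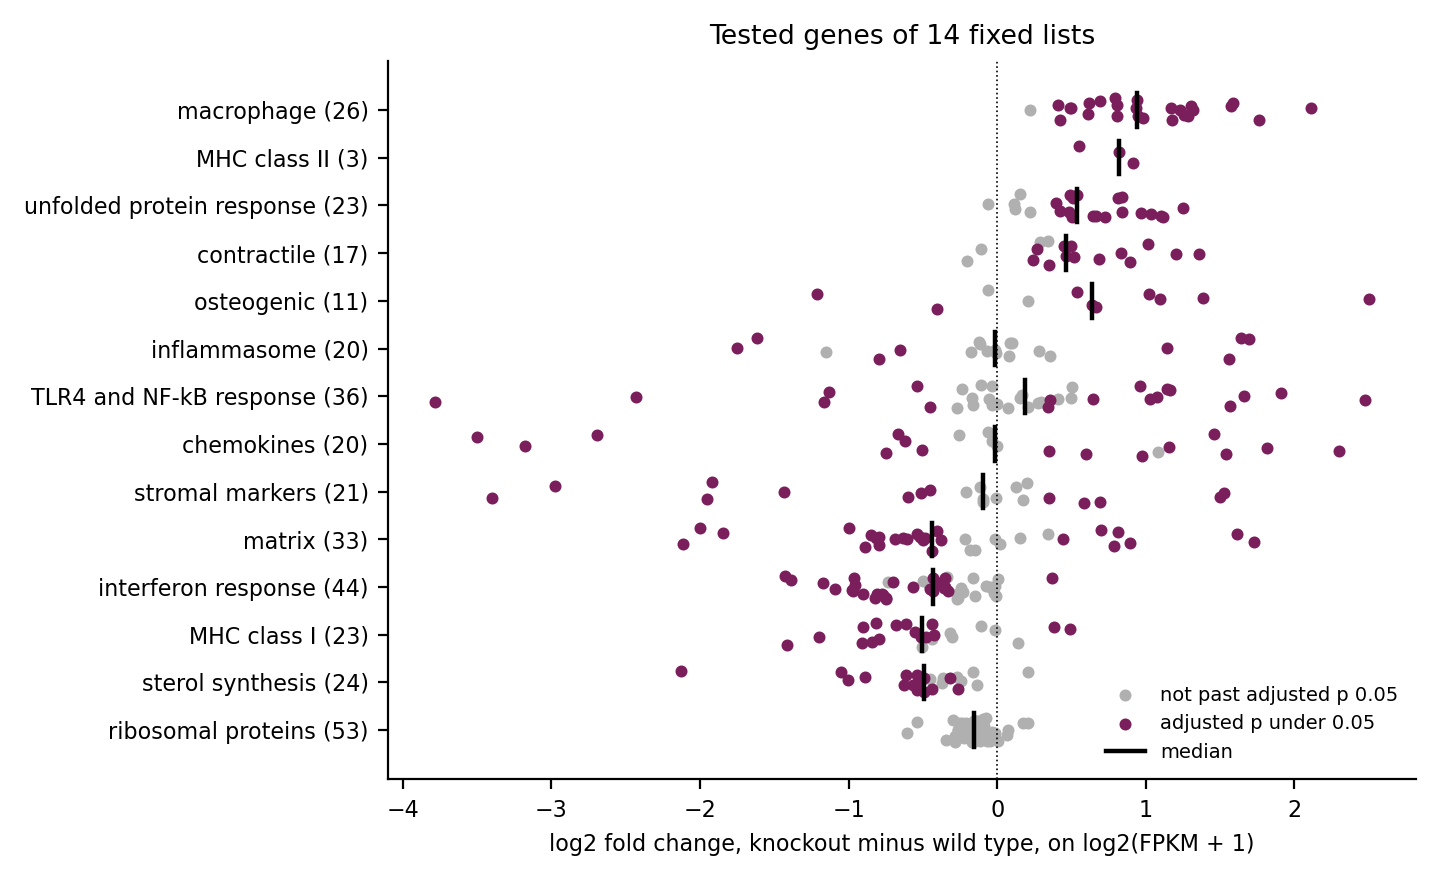
Log2 fold change (knockout minus WT, on log2(FPKM + 1)) of the tested genes of 14 gene lists, with the number of tested genes in parentheses. Each point is a gene, dark where its limma adjusted p is under 0.05 and grey otherwise, and vertical bars are list medians. The macrophage list has its median at 0.94 and the interferon list at -0.43, while chemokines spread to both sides.

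The annotation carried by the table itself was tested next. Of 274 KEGG pathways 15 passed (camera, 8 higher and 7 lower) and of 1828 GO terms 27 passed (15 higher and 12 lower). None of either passed with an estimated correlation, where the smallest adjusted p was 0.753 for KEGG and 0.998 for GO and 13 pathways and 50 terms had an unadjusted p under 0.05. Among the GO terms with the smallest p-values, 21 of 36 genes of the cellular response to interferon-beta and 14 of 23 genes of cholesterol biosynthesis were lower in the knockout. Of the KEGG pathways, leishmaniasis had the smallest p-value, with 20 of 52 genes higher and 2 lower. Of 20 genes with glutathione transferase activity, 8 fell and 1 rose (camera adjusted p = 0.00679, and adjusted p = 0.998 with an estimated correlation).

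A targeted allele can carry flanking DNA of the strain in which it was made, and the genes around Nlrp3 were therefore compared with all others. Of 187 tested genes within 10 Mb of Nlrp3 on chromosome 11, 43 (22.99%) were changed, 34 of them lower and 9 higher, against 2337 of 11948 (19.6%) elsewhere. The odds ratio was 1.23 with a 95% interval from 0.850 to 1.74, and the difference did not pass (Fisher's exact test, two-sided, p = 0.265). That test compared the share of changed genes only and took no account of direction. Among all tested genes 1264 were higher and 1117 lower, so that the changed genes near Nlrp3 leaned further to the lower side. This difference in direction was not tested.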

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

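The 1264 higher and 1117 lower genes of the limma test stayed within 1.5 times under both other pseudocounts, without a filter, under 3 scalings, without a trend, with robust eBayes and with edgeR (1483 and 1419), DESeq2 (1807 and 1675) or edgeR on counts divided by 4 (1512 and 1461). With array quality weights 2522 genes were higher and 2283 lower, and the cause was not tested; the mitochondrially encoded list (0.0203), mt-Nd1 (0.0196) and mt-Nd3 (0.0185) then passed. Requiring an FPKM of 5 left 817 higher, with fewer genes tested; a 2-fold threshold left 297 higher and 227 lower, and an adjusted p of 0.01 left 749 and 614. With 1 library left out, between 705 and 1464 genes were higher and between 583 and 1281 lower. With the replicate number as a block, 1106 genes were higher and 980 lower, and 12 lists, 16 KEGG pathways and 34 GO terms passed; Dgat2 (0.0589), Tpx2 (0.0583), Cenpa (0.107), Hoxb8 (0.0569) and the immunomodulator list (0.0577) then did not pass, and Rps20 (0.0469) and Rpl10a (0.0326) did; 4 of 6 libraries had their best partner in the other genotype at their own number, and same-numbered libraries had deviation correlations of 0.0199, 0.168 and 0.0956. Of the 13 list calls, 0 remained with an estimated correlation in camera and 22 lists passed with fry; for KEGG and GO, 0 pathways and 0 terms remained with an estimated correlation, and the cause was not tested. Of 128 named genes, 114 kept the same call in every setting that tested them, and no result reversed. Calls of Acp5, Bcl2a1b, Cenpa, Cycs, Dgat2, H2-Ab1, Ikbkg, Tcirg1 and Tpx2 were lost in at least 1 setting. With estimated correlation and fry left aside, only 17 of 32 lists kept the same call in every setting and 7 of the 13 list calls did; the osteogenic list did not pass at an FPKM of 5 (0.392), nor the MHC class II and immunomodulator lists without a filter (0.278 and 0.0514). Lists that did not pass did so in some settings: at an FPKM of 5 the stromal markers (0.0302), p53 targets (0.0494) and TLR4 signalling (0.0146); without a filter the p53 (0.0213), antioxidant (0.0246), TLR4 signalling (0.0197), protease (0.0197), cell cycle (0.0455) and lymphoid (0.0408) lists; under quantile scaling the p53 (0.0375) and antioxidant (0.0375) lists. The antioxidant list also passed without knockout replicate 2 (0.00979), proteases without WT replicate 1 (0.0486) and the respiratory chain without WT replicate 2 (0.00892) or knockout replicate 3 (0.0308). Nlrp3 had no value at an FPKM of 5 or without any of the WT libraries, because it then fell short of the expression filter. The depth of 13.3 to 16.6 M fragments (M, 1e6) limits what can be said of genes with few fragments.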

Other observations

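Several Hox genes and limb transcription factors, which vary with the body position of connective tissue, differed between the cultures. Of 25 tested Hox genes 13 fell and 3 rose (64% changed, against 19.5% of the other genes); they were singled out because they were seen to change, and neighbours in a cluster are not independent, so that no test of this share is given. All 8 tested genes of the Hoxb cluster fell, Hoxb9 from 41.1 ± 3.4 to 8.60 ± 0.48 FPKM, and Hoxc8 fell from 12.4 ± 1.8 to 3.26 ± 0.22. Hoxa11, a gene of the middle limb, rose from 0.007 to 3.93, which is uncertain because it overlaps the antisense gene Hoxa11os (0.043 to 1.07). Tbx5, a transcription factor of the forelimb, stood at 2.81 ± 0.33 in WT and at 0 in each of the 3 knockout libraries. The protocol names the femur, a bone of the hindlimb, as the source of the cells, and why the WT libraries held Tbx5 was not tested. Meox1 fell from 8.49 to 0.353, Meox2 stood at 3.36 in WT and 0.01 in the knockout, and Irx3 rose from 1.74 to 4.85. Pitx1, a gene of the hindlimb, fell from 10.4 to 6.87, Tbx15 fell from 50.3 to 30.6, and Shox2 (20.97 and 23.2) did not pass. These genes and the tests below were chosen only after the result was seen, apart from the splits of the libraries.

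The first pattern weighed is the rise of macrophage genes. A larger share of macrophages in the knockout cultures would raise these genes together, but the rise of 25 of 26 is the observation that prompted this explanation and is no test of it. A single unchanged macrophage population that only became a larger share would give 1 common ratio if no other cells expressed these genes. The FPKM ratios ran from 1.37 to 4.66, and 1 common ratio was rejected over n = 26 genes (Cochran's Q against a chi-square distribution, p = 9.77e-81, approximate because each error comes from 3 libraries per genotype). In a narrower set of n = 12 macrophage genes the FPKM ratios ran from 1.51 to 4.66, and the same test also rejected 1 common ratio. The rejection thus did not depend on the genes outside the narrower set. Expression of the macrophage genes by other cells of the cultures was not measured for either set, so that these rejections do not decide the question. A larger share of macrophages as the whole of the difference is at odds with the data, since 13 of 17 contractile genes were higher. Whether the share of macrophages differed at all is left open, since cell numbers were not measured here.

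The second pattern is a small decrease over chromosome 11, which carries Nlrp3 (median log2 fold change -0.08 over 1008 genes, 73 higher and 149 lower, adjusted p = 0.0182 over 20 chromosomes by rotation along the genome); chromosome 10 had a median of 0.093 in the opposite direction (100 higher and 37 lower, adjusted p = 0.328), seen in each knockout library (0.103, 0.088 and 0.073). Flanking DNA of another strain within 20 Mb of Nlrp3 does not account for all of the decrease. The 625 genes more than 20 Mb away had a median of -0.069, just under the lower bound of the rotations (-0.064). A longer flank, or a part played by DNA near Nlrp3, is not excluded, because the extent of the flank is not known. The 20 Mb segment that holds Nlrp3 had a median of -0.13. GC content does not account for all of the decrease either, since the chromosome 11 median was -0.064 after a fit on GC. A lower dose of the whole chromosome in part of the cells would place every segment of 20 Mb under the median of all genes, and 7 of 7 were, but so were 5 of 5 on chromosome 17, and 0 of 7, 0 of 6 and 0 of 5 were on chromosomes 10, 13 and 18, so that the cause is left open. The knockout libraries differed from all genes by -0.098, -0.103 and -0.046.

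The third pattern is the change of Hox genes. The shift of chromosome 11, which holds the Hoxb cluster, had a median of only -0.08, against -1.282 for the Hoxb genes. A uniform shift of that size alone falls short of the Hoxb decreases. The bootstrap interval of the Hoxb median (-1.73 to -0.916) is no test of this. It treats 8 neighbouring genes as independent, and these genes were singled out because they were seen to change. Cultures that started from cells of other body positions could give it, and 8 of 17 Hox genes outside the Hoxb cluster changed. An effect of the genotype would give the same, so that these data cannot tell them apart. The origin of the cultures is a limit for all genes that differed between the genotypes, and not for Hox genes alone.

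All 10 splits of the 6 libraries into 3 and 3 were examined, which are too few to exclude chance. Each split other than the genotypes mixes libraries of both, so that the difference between genotypes enters the spread within its groups. The counts of the other splits are therefore not the counts that chance alone would give. For changed genes 1 split gave a result as large (the genotypes, 2381; highest other 3), for gene lists 1 (13; highest other 10), for KEGG pathways 2 (15; highest other 16) and for GO terms 3 (27; highest other 47).

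The Y-linked genes Ddx3y and Eif2s3y stood at 4.99, 6.65 and 2.14 and at 6.84, 7.51 and 3.33 FPKM in knockout replicates 1, 2 and 3, against 3.56, 3.70 and 3.47 and 5.31, 5.85 and 6.59 in WT replicates 1, 2 and 3. Kdm5d stood at 1.74, 1.87 and 1.24 in the knockout libraries, against 1.84, 1.95 and 2.06 in WT, and Uty at 1.02 ± 0.24 against 1.22 ± 0.16, with 0.78 in knockout replicate 3. Xist stood between 0.01 and 0.05 in every library. Gapdh ranged from 36.5 to 113.8 between libraries. The genes of this paragraph were chosen after their values were seen.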
